A study of Mus musculus with 12 samples.

How the data were processed

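Bulk RNA sequencing measured gene expression in liver macrophages of mice. Cells were enriched from digested livers with beads carrying an antibody to F4/80, a surface protein of mouse macrophages, so the preparation is an enrichment and not a sorted population. The 12 libraries fall into 4 groups of 3. Wild-type (WT) and sph/sph mice received either saline or 20 mg/kg of an agonistic antibody to CD40 by intraperitoneal injection, and cells were taken 30 h later. Sph/sph mice have spherical, fragile red cells and haemolytic anaemia. The series' design text counts mice, 3 per genotype and treatment, so the replicates are taken as separate animals. The labels describe male mice of 8 to 10 weeks.

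The values used are read counts per gene as deposited, 1 column per library, with no normalization by the authors that the values show. Per the submitters' processing notes, STAR 2.7.0e, SAMtools 1.9 and featureCounts were used with genome build GRCm38.p5; the roles of the tools, the annotation release, the strand setting and the treatment of reads that map to several places are not given in the sources used here. Libraries were made with a stranded TruSeq kit per the labels' protocols. Because the strand setting of the counting is not given, values of genes that overlap a gene on the other strand are uncertain, as are values of near-identical copies such as the haemoglobin genes Hba-a1 and Hba-a2. The table's columns name the treatment and the genotype but carry no replicate number. The columns of the control genotype call it heterozygous, whereas every label calls it wild type; it is called WT here after the labels, and a heterozygous control genotype is not excluded. Letters A to C name the libraries within a group in the order of the columns, and libraries were not paired by letter. The A libraries of WT and sph/sph share an identification number in each treatment, whose meaning is not given; B and C are not linked in this way.

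The table lists 25700 Ensembl gene identifiers, of which 25587 matched a gene symbol in a name table for the mouse; 8 symbols belong to more than 1 identifier, and 6872 genes had a count of 0 in every library. Coordinates are from a GENCODE annotation of GRCm38, counted from 1. Depth ran from 14991250 counts (sph/sph anti-CD40 B) to 18984067 counts (sph/sph saline C) per library. At these depths a gene with 0 counts in the 3 libraries of a group is given a floor of 3 counts over the group, and a ratio to it is a lower bound; ratios to a group with 1 to 3 counts carry a counting interval. Values of the interaction carry none. Intervals and floors cover counting error only.

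Calls came from edgeR 4.0.16 in R 4.3.3: filterByExpr by group (13844 genes tested), TMM normalization, a robust quasi-likelihood fit of all 12 libraries with a mean per group and no further covariate, and quasi-likelihood F tests. A gene was called at a Benjamini-Hochberg adjusted p under 0.05. The common biological coefficient of variation was 0.382. Contrasts were sph/sph against WT under saline, anti-CD40 against saline in WT, the same in sph/sph, sph/sph against WT under anti-CD40, the interaction (the response of sph/sph minus that of WT) and the mean of both responses. Log2 folds are edgeR's. Their standard errors (SE) are approximate: the size of the log2 fold divided by the square root of the F statistic. Levels are CPM, that is, read counts scaled to a common library total, on TMM-scaled library sizes with the SD over libraries. Negative log2 folds mean lower in the first-named group.

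In all, 29 gene lists were fixed, 18 of cell programs, 1 of genes that respond to tissue dissociation and 10 of marker genes of other cells that such a preparation could hold. For each list the text gives the members that rose and fell, called over all genes tested, and the number called when adjusted over the list alone. Lists were tested with camera (limma 3.58.1, preset inter-gene correlation 0.01), which compares a list with all other genes, with adjustment over the 29 lists. Camera with an estimated correlation and fry, which asks whether a list's genes move one way on balance and makes no comparison with other genes, were the alternatives. The preset correlation gives many calls here: other splits of the same libraries gave a median of 16 or 17 called lists, so camera's calls are printed with the p for an estimated correlation, and the counts of members carry the description. The calls that held with an estimated correlation were the erythroid and NRF2 lists for genotype under saline, the Kupffer cell list for anti-CD40 in WT, for genotype under anti-CD40, for the interaction and for the mean response, and for genotype under anti-CD40 also the heme and iron, NRF2 and LXR lists. Without sph/sph anti-CD40 C those of the NRF2 list, of the LXR list and of the Kupffer cell list in WT did not hold; the mean response was not tested in this way. Of the list members, 3 matched no gene in the table. Lists share members: 10 phagocytosis, 9 anti-inflammatory and 7 Kupffer cell genes are also in other lists, Vsig4 and Marco among them. Such a gene counts in each of its lists, so results of these lists are not separate.

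A response score per library was the mean log2 CPM (prior count 2) of 1476 genes that rose minus that of 1289 genes that fell in the mean response, with a log2 fold of at least 1 in size. In this balanced design the mean response is independent of the difference between the responses if the groups have equal spread. The score's SD ran from 0.108 in WT saline to 0.535 in sph/sph anti-CD40, so the independence is approximate. The difference between the responses was tested with an exact two-sided permutation of the genotypes within each treatment (400 arrangements). The permutation supposes no effect of genotype in either treatment, which is more than equal responses. With 1 library left out the design is not balanced either, which also breaks the independence. Differences between 2 groups of 3 cannot reach an exact p under 0.1. Correlations of log2 folds are across genes, which are not independent replicates, and the contrasts compared share no library.

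Genes named in the text follow a rule: for each of the 4 comparisons of pairs of groups, the 10 highest and 10 lowest log2 folds among called genes with a mean of at least 10 CPM in the higher group and no overlap between the libraries, leaving out unnamed genes, antigen receptor segments and markers of other cells; the same number each way for the interaction, without the overlap condition; up to 4 members of each list with the largest called folds; and 22 genes named in every comparison, among them Cd40, Hmox1, Marco, Clec4f, H2-Aa, Tnf, Il10 and Il12b. Results of some genes that meet the rule are not reported. Any other gene named was chosen after its values were seen.

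Alternatives were DESeq2 size factors, DESeq2 1.42.0, limma-voom with library quality weights, a fit without the robust option, no filter or a stricter filter on low counts (1 CPM in 3 libraries and a mean count of 50), removal of other cells' and mitochondrial genes, fits of only the 6 libraries compared, a log2 fold of at least 1, and leaving out each library in turn. The comparisons, tests, lists, the rule for named genes and these alternatives were chosen before the data were examined. A term for sex was added after seeing the data. Replicates within a group differed by more than sampling noise: the smallest chi-square per degree of freedom between 2 libraries of a group was 34.3, so no library appears under 2 names.

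The code was tested on simulated counts with 100 genes changed 2-fold and 100 changed 4-fold. For genotype under saline it recovered 21 of the former and 71 of the latter with 1 false call among 13704 genes. For anti-CD40 in WT it recovered 12 and 64, with 3 false calls among 13687 genes. Over 13688 genes each, it recovered 13 and 65 for anti-CD40 in sph/sph (4 false calls), 17 and 62 for genotype under anti-CD40 (3 false calls), and 1 and 30 for the interaction (1 false call). The list made to change was called in each of the 5 simulations, and none of 28 random lists was. Simulated genes varied independently of each other, so the random lists say nothing about false calls of lists whose genes are correlated. An interaction of 2-fold is therefore mostly out of reach with 3 libraries per group. Figures were drawn with matplotlib 3.10.9.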

Results

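Gene expression was measured by RNA sequencing in liver macrophages, enriched with beads for the surface protein F4/80, from wild-type (WT) and sph/sph mice given saline or an agonistic antibody to CD40. CD40 is a receptor of macrophages, dendritic cells and B cells that drives inflammatory activation when engaged. Sph/sph mice have fragile red cells, which are taken up and degraded by liver and spleen macrophages. The series' title names the question, whether the uptake of red cells steers liver macrophages towards an anti-inflammatory state. Each of the 4 groups (WT saline, sph/sph saline, WT anti-CD40 and sph/sph anti-CD40) held 3 libraries. Total counts per library ran from 15586731 to 18006254 in WT saline, from 15931077 to 18984067 in sph/sph saline, from 15883477 to 18940990 in WT anti-CD40 and from 14991250 to 16474784 in sph/sph anti-CD40. In all, 13844 genes were tested. On the first principal component (49.3% of the variance) WT saline libraries lay between -67.3 and -53.0 and WT anti-CD40 libraries between 104.3 and 133.5. Sph/sph saline libraries lay between -84.4 and -51.4 and sph/sph anti-CD40 libraries between -8.09 and 8.85.

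The first comparison, sph/sph against WT under saline, asks how lasting destruction of red cells alters liver macrophages without further stimulus. Hmox1, the enzyme that breaks down heme (ENSMUSG00000005413, chromosome 8, 75093621 to 75100589), rose 7.52-fold, from 1455 ± 496 to 10940 ± 592 CPM (SD, n = 3 per group; edgeR adjusted p = 0.00608). Marco, a scavenger receptor (ENSMUSG00000026390, chromosome 1, 120474538 to 120505024), rose 17.3-fold, from 654 ± 339 to 11330 ± 1728 CPM (edgeR adjusted p = 0.00955). Spic, a transcription factor of iron-recycling macrophages, rose 3.84-fold to 348 ± 53.5 CPM (edgeR adjusted p = 0.0353). H2-Aa, which presents antigen on MHC class II (ENSMUSG00000036594, chromosome 17, 34282744 to 34287823), fell from 2296 ± 1358 to 245 ± 166 CPM, 9.38-fold (edgeR adjusted p = 0.0328). In all, 222 genes were higher and 60 lower in sph/sph.

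Of the 25 measured genes of heme and iron handling, 4 rose and none fell (10 and 1 when adjusted over the list alone). They were Hmox1, Tfrc (log2 fold 2.12 ± 0.36, SE), the transferrin receptor, Spic (1.94 ± 0.40) and Slc48a1 (1.82 ± 0.24), which moves heme out of the lysosome. The iron exporter Slc40a1 stood at 5987 ± 1183 CPM in WT and 6084 ± 1276 CPM in sph/sph. Camera called the list (adjusted p = 3.09e-07; adjusted p = 0.171 with an estimated correlation). Among 32 targets of NRF2, the regulator of the oxidative stress response, 6 rose and none fell (12 when adjusted over the list alone), led by Me1 (2.56 ± 0.45), Mgst1 (1.74 ± 0.18), Gstm1 (1.73 ± 0.31) and Gclm (1.60 ± 0.28); camera called it (adjusted p = 1.72e-13; adjusted p = 0.0286 with an estimated correlation, and 0.0546 without sph/sph anti-CD40 C). Of 34 genes of glycolysis and the hypoxia response 6 rose and none fell (17 when adjusted over the list alone), among them Egln3 (4.14 ± 0.31), Ankrd37 (3.65 ± 0.50), the lactate transporter Slc16a3 (2.62 ± 0.57) and the glucose transporter Slc2a1 (2.38 ± 0.43). The test of this list gave camera adjusted p = 2.62e-16, and adjusted p = 0.171 with an estimated correlation. With sph/sph anti-CD40 C left out 18 glycolysis and 8 heme and iron genes rose.

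Of 12 genes of MHC class II presentation 4 fell and none rose (7 when adjusted over the list alone): H2-Aa, H2-Eb1 (log2 fold -3.16 ± 0.67), H2-Ab1 (-3.14 ± 0.63) and Cd74, the invariant chain (-2.96 ± 0.63). The list passed (camera adjusted p = 5.51e-09; adjusted p = 0.171 with an estimated correlation). H2-Aa varied between libraries, at 3691, 2217 and 978 CPM in WT saline A, B and C and at 431, 113 and 190 CPM in sph/sph saline A, B and C. Large falls outside the lists were those of Slc27a6, a fatty acid transporter (-6.24 ± 0.90), Cxcl14 (-4.46 ± 0.64) and Cd207, the C-type lectin langerin (-3.94 ± 0.55), which went from 1324 ± 194 to 86.1 ± 6.45 CPM. Tmem176b fell by 2.60 and Gpm6b by 2.38 on the log2 scale. Large rises outside the lists were those of Lrrc14b (7.30 ± 1.03), Apol11b (7.02 ± 0.94), Epx, a granule protein of eosinophils (6.76 ± 1.37), Ypel4 (6.61 ± 1.15), Wasf1 (6.40 ± 0.46) and Elfn1 (5.77 ± 0.42).

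Of 29 genes that define Kupffer cells, the resident macrophages of the liver, 3 rose under saline (Marco, Vcam1 at 1.98 ± 0.31 and Gfra2 at 1.34) and none fell (3 and 1 when adjusted over the list alone). The median of this list was -0.10 and its mean 0.07, and camera did not call it (adjusted p = 0.942). Clec4f stood at 10030 ± 304 CPM in WT and 7696 ± 1834 CPM in sph/sph, and Vsig4 at 3207 ± 372 and 3105 ± 464 CPM. Of the 39 phagocytosis and scavenger receptor genes 2 rose, Marco and Colec12 (3.09 ± 0.32), and none fell (the same when adjusted over the list alone; median -0.05, mean 0.13, camera adjusted p = 0.405). None of the 34 inflammatory cytokine and chemokine genes was called, nor any of the 38 interferon-gamma response genes or the 35 monocyte genes, over all genes or over the list alone. In the fit without sph/sph anti-CD40 C 2 inflammatory, 2 NF-kB and CD40 signalling and 1 monocyte gene fell. At an unadjusted p under 0.05 the comparison held 1817 genes, against 282 called by edgeR, 823 by DESeq2 and 1943 by limma-voom. Of 38 lysosome genes 3 rose (6 when adjusted over the list alone), Gpnmb (3.12 ± 0.68), Cd63 (2.41 ± 0.49) and Gla (1.79), with camera adjusted p = 5.43e-05 and adjusted p = 0.709 with an estimated correlation.

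Genes of other programs were called under saline as well. Of 27 LXR target and lipid handling genes 2 rose, Fabp5 (2.52 ± 0.29), a carrier of fatty acids, and Lpl, the lipoprotein lipase (1.60 ± 0.33), with 8 when adjusted over the list alone. Sqle (2.09 ± 0.43) was the 1 of 26 cholesterol synthesis genes that rose (2 when adjusted over the list alone). Camera called both lists (adjusted p = 0.00189 and 0.000613; adjusted p = 0.237 and 0.63 with an estimated correlation). Pparg (2.18 ± 0.27) rose among 27 anti-inflammatory genes, Asns (3.23 ± 0.63) among 27 unfolded protein response genes, and Fosb (-1.69 ± 0.34) fell among 32 immediate-early and dissociation genes; adjusted over the list alone 3 rose, 1 rose and 1 fell, and 1 fell. On all libraries none of 34 interferon-stimulated, 37 NF-kB and CD40 signalling, 23 MHC class I or 40 cell cycle genes was called, over all genes or over the list alone. The interferon-stimulated genes had a median of -0.30 (camera adjusted p = 0.0113; adjusted p = 0.96 with an estimated correlation).

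Markers of other cells differed too. Of 35 erythroid genes 25 rose and none fell (35 when adjusted over the list alone), with a median log2 fold of 5.41; camera called the list (adjusted p = 4.87e-67; adjusted p = 0.0192 with an estimated correlation). Its summed level was 443 ± 131 CPM in WT saline and 9040 ± 1456 CPM in sph/sph saline. Kel rose (7.78), as did Epb42 (6.44) and Hemgn (6.96), all of red cell precursors, and Trim58 was at least 47.5-fold higher in sph/sph than in WT, where it had 0 counts. The haemoglobin genes took 0.497% to 0.817% of all counts in sph/sph saline against at most 0.0308% in WT. Of 26 neutrophil genes 1 rose (8, with 2 fallen, when adjusted over the list alone), Fcnb (at least 13.7-fold higher, with 0 counts in WT), and 1 fell, Mmp9 (-4.10 ± 0.62). The megakaryocyte list had a median of 2.10 and the endothelial list of -0.66, with no gene called over all genes. Camera called both lists (adjusted p = 4.81e-05 and 0.00244), but not with an estimated correlation (adjusted p = 0.63 and 0.954). Leaving out 1 library moved the 282 calls to 120, 73 and 90 (WT saline A, B and C), to 137, 126 and 149 (sph/sph saline A, B and C) and to 539 (sph/sph anti-CD40 C). Hmox1 was not called without WT saline B (edgeR adjusted p = 0.0514), nor H2-Aa without WT saline A or B or sph/sph saline B or C (edgeR adjusted p = 0.11, 0.105, 0.109 and 0.127), nor Spic without any 1 of the 6 saline libraries (edgeR adjusted p from 0.072 to 0.179), WT anti-CD40 C (0.0598) or sph/sph anti-CD40 A (0.0501). H2-Eb1, H2-Ab1 and Cd74 lost their calls in the same fits as H2-Aa, among others. Slc16a3, Gpnmb, Cd63, Gla, Lpl, Slc2a1, Me1, Gclm, Gstm1, Gfra2, Epx, Fcnb, Sqle, Asns, Fosb, Tfrc and Vcam1 were each not called in 3 or more of the 12 fits. With a term for sex, added after seeing the data, Slc16a3, Gpnmb, Gla and Sqle were not called.

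**Figure D1:**
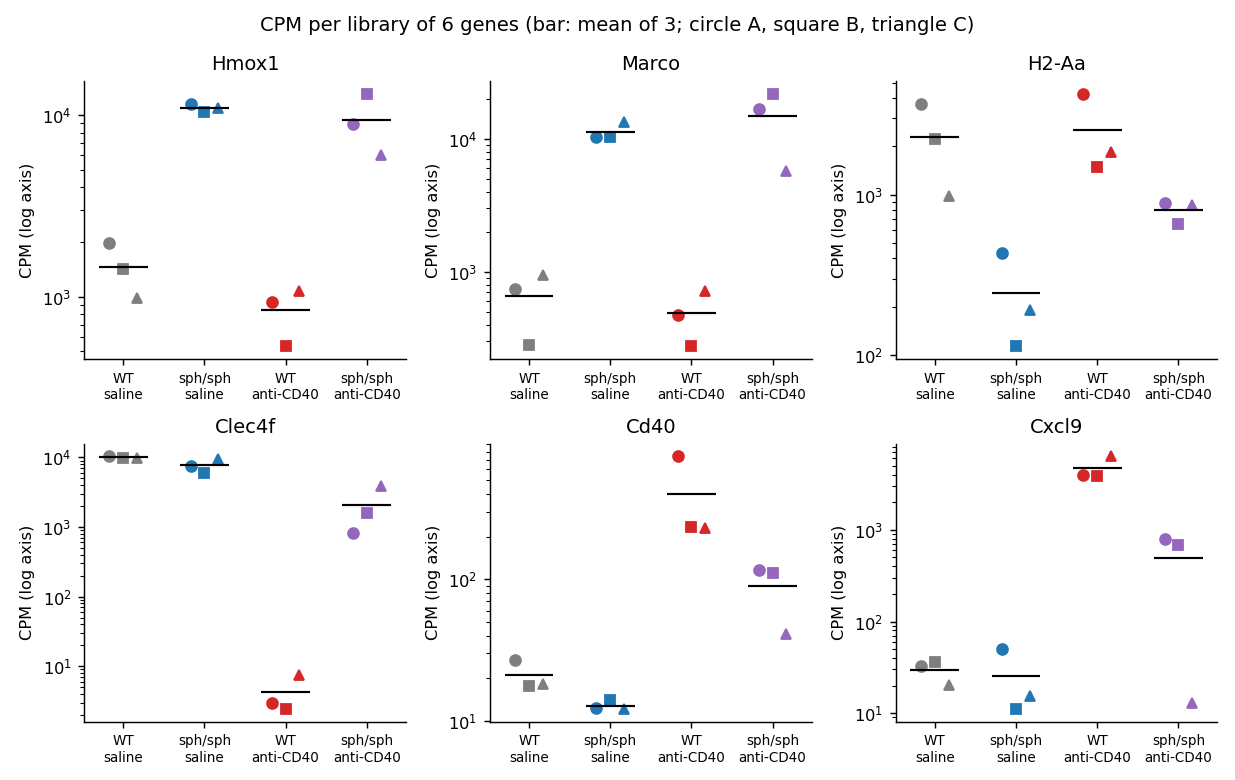
CPM of 6 genes in each library on a log axis, by group; the bar is the mean of 3 libraries and the symbols mark libraries A, B and C. Hmox1 and Marco lie higher in both sph/sph groups than in both WT groups, Clec4f is at 4.29 CPM in WT anti-CD40 and at 2099 CPM in sph/sph anti-CD40, and Cxcl9 is at 12.8 CPM in sph/sph anti-CD40 C.

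The second comparison, anti-CD40 against saline in WT, describes the response to CD40 engagement in the cells enriched from WT livers. Inflammatory genes rose steeply: Cxcl9, a chemokine induced by interferon-gamma (ENSMUSG00000029417, chromosome 5, 92321347 to 92328079), went from 29.6 ± 8.44 to 4699 ± 1398 CPM (159-fold; SD, n = 3 per group; edgeR adjusted p = 0.00215). Tnf rose 88.3-fold to 304 ± 289 CPM (edgeR adjusted p = 0.00261). At the same time 25 of 29 genes that define Kupffer cells fell. Clec4f, a lectin of Kupffer cells (ENSMUSG00000014542, chromosome 6, 83644542 to 83656187), went from 10030 ± 304 to 4.29 ± 2.82 CPM (2323-fold; edgeR adjusted p = 1.75e-05), and Cd163, the receptor for haemoglobin bound to haptoglobin (ENSMUSG00000008845, chromosome 6, 124304656 to 124330527), from 2432 ± 629 to 0.529 ± 0.521 CPM (4784-fold; edgeR adjusted p = 1.59e-05). In all, 2690 genes rose and 2730 fell.

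Of the 29 Kupffer cell identity genes 25 fell and none rose (the same when adjusted over the list alone), with a median log2 fold of -4.04. Besides Clec4f they included Vsig4 (-10.31 ± 1.26), the transcript of a complement receptor, Fabp7 (-7.47), C6 (-7.36), Timd4 (-4.42 ± 0.73), a receptor for dying cells, and Adgre1 (-4.34 ± 0.57), which encodes F4/80 itself. The beads captured cells by F4/80, so which cells they held may have changed with the treatment. The protein was not measured. The list passed (camera adjusted p = 2.1e-32; adjusted p = 0.0253 with an estimated correlation, and 0.173 without sph/sph anti-CD40 C). Of 39 phagocytosis and scavenger receptor genes 23 fell and 4 rose (23 and 5 when adjusted over the list alone), among them Cd163, Vsig4, Itgb5 (-5.43) and the complement gene C1qc (-4.85). This list had camera adjusted p = 3.43e-07 and adjusted p = 0.263 with an estimated correlation. Of 27 LXR target and lipid handling genes 15 fell and 3 rose (the same when adjusted over the list alone), with falls of Pltp (-5.27 ± 0.28), Apoc1 (-4.68) and Cyp27a1 (-4.44) and a rise of Ch25h, which makes 25-hydroxycholesterol (10.08 ± 0.80). Its camera adjusted p was 4.94e-06, and adjusted p = 0.152 with an estimated correlation.

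Of the 25 heme and iron genes 10 fell and 6 rose (12 and 6 when adjusted over the list alone), Slc40a1 going from 5987 ± 1183 to 127 ± 56.1 CPM (edgeR adjusted p = 1.81e-05), Hfe falling by 4.98 and Lcn2 rising by 5.42 on the log2 scale; Hmox1 stood at 850 ± 284 CPM against 1455 ± 496 CPM (edgeR adjusted p = 0.122). Of 38 lysosome genes 14 fell and 4 rose (14 and 5 when adjusted over the list alone), and of 32 NRF2 targets 14 fell and 5 rose (the same when adjusted over the list alone), with Slc7a11 at 8.26 and Ephx1 at -5.43. Camera gave adjusted p = 0.00187, 0.00104 and 0.00697 for these lists, and adjusted p = 0.42, 0.696 and 0.42 with an estimated correlation.

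Of the 34 inflammatory cytokine and chemokine genes 24 rose and 2 fell (26 and 3 when adjusted over the list alone). Nos2, the inducible nitric oxide synthase, rose by 9.91, Ptgs2 by 9.28 and Cxcl11 by 8.83 on the log2 scale. Lif had 1 count in WT saline and rose by a ratio of 257 (counting interval 45.8 to 10190). Il12b rose 158-fold (edgeR adjusted p = 0.00138) and Ccl2 56.0-fold (edgeR adjusted p = 0.00276), whereas Il10 stood at 3.08 ± 0.582 and 3.02 ± 0.811 CPM and Il1b at 130 ± 34.7 and 181 ± 132 CPM. Of 38 interferon-gamma response genes 28 rose and 3 fell (the same when adjusted over the list alone), with Ubd at 11.28 ± 1.82, Upp1 at 6.81, Tgtp1 at 6.17 and Socs1 at 5.06. Of 37 NF-kB and CD40 signalling genes 26 rose and 1 fell (26 and 2 when adjusted over the list alone), with Ccl22 (8.14), Traf1 (7.76), Bcl2a1d (4.42) and Cd40 itself (19.2-fold; edgeR adjusted p = 0.000347). Of 23 MHC class I presentation genes 18 rose and none fell (19 when adjusted over the list alone), led by H2-Q7 (4.01 ± 0.46) and H2-Q6 (3.86). Camera called these lists with adjusted p = 3.36e-07, 9.15e-09, 4.1e-09 and 4.44e-09, in that order. Their values were adjusted p = 0.42, 0.465, 0.42 and 0.42 with an estimated correlation.

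Of 34 interferon-stimulated genes 13 rose and 1 fell, Isg15 by 3.98 ± 0.89, and of 34 genes of glycolysis and the hypoxia response 24 rose and 3 fell, Eno2 by 6.08 and Slc16a3 by 3.55. Of 35 monocyte genes 17 rose and 4 fell, with Clec4e at 8.26 ± 1.46, Ly6c2 at 7.32 ± 1.12 and Ly6c1 at 6.97 ± 0.44. Of 32 immediate-early and dissociation genes 16 rose and 3 fell, Hspa1b by 4.63, of 27 unfolded protein response genes 10 rose and 2 fell, and of 40 cell cycle genes 5 rose and 2 fell. The anti-inflammatory list went both ways, with 8 risen and 9 fallen of 27 (Ccl22 up, Folr2 at -6.05, Trem2 at -5.81). Of 12 MHC class II genes 4 rose, H2-Eb2 by 5.45 and H2-Oa by 4.34, and 1 fell, while H2-Aa stood at 2296 ± 1358 and 2532 ± 1509 CPM. Of 26 cholesterol synthesis genes 6 rose and 2 fell, Sqle by 1.96 (camera adjusted p = 0.146). When adjusted over the list alone the numbers risen and fallen were 13 and 1, 25 and 5, 19 and 5, 20 and 4, 11 and 2, 0 and 2, 8 and 9, 4 and 1, and 6 and 2, in the order named. Camera called the interferon-stimulated, glycolysis, monocyte, immediate-early, unfolded protein response and cell cycle lists (adjusted p = 0.000483, 1.07e-06, 5.94e-05, 0.000548, 0.0316 and 0.0222; adjusted p = 0.697, 0.42, 0.547, 0.42, 0.696 and 0.713 with an estimated correlation).

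Markers of other cells moved with the treatment in WT. Of 37 T and NK cell genes 34 rose and 1 fell (the same when adjusted over the list alone; median 6.27), with Prf1 at 11.17 ± 1.76 and Gzmb at 9.30, and their summed level went from 163 ± 24.2 to 1973 ± 1629 CPM (604, 3774 and 1540 CPM in libraries A, B and C). Camera's adjusted p was 1.27e-10, and adjusted p = 0.42 with an estimated correlation. Of 26 neutrophil genes 14 rose and none fell (S100a9 by 5.37), of 24 dendritic cell genes 8 rose and 2 fell (Ccr7 by 6.96), and of 26 B cell genes 9 rose and 1 fell. Hepatocyte genes fell in 10 and rose in 1 of 36, and stellate cell genes fell in 9 and rose in 1 of 24, with medians of -1.12 and -1.65. Several of the genes with the largest folds are known from NK and cytotoxic T cells: Gzmc was at 47.8 ± 32.0 CPM after anti-CD40 with 1 count in WT saline (a ratio of 2582, with a counting interval of 463 to 102000), Klra7 was at least 297-fold higher and Klrg1 at least 198-fold higher. Cst7 rose by 10.26 ± 0.84, Tnfrsf9 by 9.98 ± 1.06, and Cd207 fell by 13.07 ± 0.85 on the log2 scale. Which cells expressed these genes was not tested. Without WT saline B 1647 genes rose; no other library that was left out moved either count by over 1.5 times. Leaving out sph/sph anti-CD40 C made 25 the number of interferon-stimulated genes that rose (1 fell), and 18 that of B cell genes (3 fell).

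The third comparison asks for the same response in sph/sph mice. Traf1, an adaptor of CD40 signalling (ENSMUSG00000026875, chromosome 2, 34941750 to 34961772), went from 2.42 ± 1.01 to 72.8 ± 47.5 CPM (30.1-fold; SD, n = 3 per group; edgeR adjusted p = 0.0237). Il4i1, an amino acid oxidase of activated myeloid cells, rose 25.9-fold to 188 ± 92.9 CPM (edgeR adjusted p = 0.00757), and Cd40 rose by 2.81 ± 0.52 on the log2 scale to 89.4 ± 41.9 CPM (edgeR adjusted p = 0.0475). Cst7 (log2 fold 4.55 ± 0.66), the endocytic receptor gene Ly75 (4.55 ± 0.74), H2-Eb2 (4.52 ± 0.62), Gpr183 (4.38 ± 0.75), Gpr18 (4.19 ± 0.51) and Ms4a4c (3.64 ± 0.59) rose. Cebpa, a transcription factor of myeloid cells (-1.35 ± 0.24), Zdhhc14 (-2.01 ± 0.38), Arhgap39 (-1.41 ± 0.20), Dcxr (-1.37 ± 0.23) and the lysosomal protease gene Ctsf (-1.29 ± 0.25) fell. H2-Eb2 was at 3.66 and Gpr183 at 3.18 without library C, which held the most B cell transcripts of its group. With the term for sex Cebpa, Zdhhc14, Ctsf, Icosl and Ly6c1 were not called, and 73 of the 108 calls were shared. In all, 80 genes rose and 28 fell.

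Of the 37 NF-kB and CD40 signalling genes 5 rose and none fell (21 when adjusted over the list alone): Traf1, Cd40, Icosl (2.81), Nfkbie (2.27) and Nfkb2 (2.11). Camera called the list (adjusted p = 4.32e-13; adjusted p = 0.41 with an estimated correlation). Of 35 monocyte genes 3 rose, among them Ms4a4c and Ly6c1 (2.38), with 16 risen and 1 fallen when adjusted over the list alone (23 over all genes without library C). No inflammatory or interferon-gamma response gene and none of the Kupffer cell genes was called over all genes, but adjusted over the list alone 15 of 34 and 23 of 38 rose and 11 of 29 fell. Cxcl9 stood at 25.4 ± 21.2 CPM under saline and 494 ± 420 CPM under anti-CD40 (edgeR adjusted p = 0.0949), Tnf at 3.06 ± 0.759 and 47.5 ± 46.0 CPM, Il10 at 3.37 ± 1.51 and 36.8 ± 30.7 CPM (edgeR adjusted p = 0.105), and Clec4f at 7696 ± 1834 and 2099 ± 1581 CPM (edgeR adjusted p = 0.115). Hmox1 stood at 10940 ± 592 and 9361 ± 3555 CPM and Marco at 11330 ± 1728 and 14780 ± 8222 CPM. Over all genes 2901 had an unadjusted p under 0.05; edgeR called 108, DESeq2 1308 and limma-voom 2182.

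The inflammatory, interferon-gamma response and Kupffer cell lists had medians of 2.34, 1.51 and -0.96 (camera adjusted p = 1.38e-08, 3e-11 and 2.99e-11; adjusted p = 0.41, 0.41 and 0.179 with an estimated correlation). H2-Eb2 was the 1 of 12 MHC class II genes called over all genes, H2-Q7 (2.25 ± 0.43) the 1 of 23 MHC class I genes and Il1r2 (4.72 ± 0.80), a decoy receptor for interleukin 1, the 1 of 27 anti-inflammatory genes. Adjusted over the list alone 8 MHC class II and 5 MHC class I genes rose, and of the anti-inflammatory genes 5 rose and 5 fell (median -0.60, mean 0.19, camera adjusted p = 0.173). No LXR target, lysosome, phagocytosis, heme and iron, or glycolysis gene was called over all genes; adjusted over the list alone 9 LXR targets fell and 1 rose, 6 lysosome and 2 phagocytosis genes fell, no heme and iron gene was called and 3 glycolysis genes rose. B cell genes rose in 13 of 26 when adjusted over the list alone, with 5682 CPM in library C against 554 and 260 CPM in A and B. The T and NK cell list had a median of 2.65 (camera adjusted p = 2.41e-06; adjusted p = 0.565 with an estimated correlation), and 1.23 without library C (camera adjusted p = 0.203). The neutrophil and stellate cell lists had medians of 1.24 and -1.20 (camera adjusted p = 0.000609 and 0.000551, and adjusted p = 0.41 and 0.569 with an estimated correlation). Without library C these medians were 0.99 and -2.00 (camera adjusted p = 0.00432 and 0.00121).

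Library C of sph/sph anti-CD40 stood apart from A and B of its group. It held 12.8 CPM of Cxcl9 against 788 and 683 CPM in A and B, 2.91 CPM of Tnf against 44.8 and 94.8 CPM, and 1.35 CPM of Il10 against 54.9 and 54.1 CPM (sph/sph saline means were 25.4, 3.06 and 3.37 CPM). Clec4f was at 3869 CPM against 828 and 1601 CPM. The interferon-gamma list summed to 13220, 13120 and 2848 CPM in A, B and C, against 11710 to 17190 CPM in WT anti-CD40. Without library C 1382 genes rose and 990 fell, among them 20 inflammatory, 28 interferon-gamma response, 22 NF-kB, 22 interferon-stimulated and 15 MHC class I genes that rose and 7 Kupffer cell genes that fell. In that fit 23 monocyte and 19 glycolysis genes rose, 9 LXR targets and 6 lysosome genes fell, and 6 phagocytosis genes fell and 3 rose. Of the markers of other cells 8 hepatocyte genes fell, 7 dendritic cell genes fell and 1 rose, and 5 neutrophil genes rose. Cxcl9 (log2 fold 4.85 ± 0.61; edgeR adjusted p = 0.0018), Tnf (22.6-fold; 0.00652), Il10 (4.00 ± 0.38; 0.000557), Nos2 (6.48 ± 1.31; 0.0116), Ccl2 (3.94 ± 0.34; 0.000469) and Clec4f (-2.67 ± 0.53; 0.0106) were then called. On all libraries DESeq2 called these 6 genes (adjusted p = 0.000342, 0.000923, 0.00275, 0.00154, 0.0039 and 0.00964). The count of 108 was 43, 47 and 29 without WT saline A, B and C, 228, 48 and 66 without WT anti-CD40 A, B and C, and 1 and 17 without sph/sph anti-CD40 A and B. Without sph/sph saline A, B or C edgeR called 0 genes, with 1994, 2712 and 1812 genes at an unadjusted p under 0.05; with only the 6 libraries compared it also called 0, with 2056 such genes, so that none of the genes named was called in these 4 fits. Traf1 was also not called without sph/sph anti-CD40 A or B. Cd40 was not called in these fits (edgeR adjusted p = 0.161 and 0.11), without any 1 WT saline library (0.0748 to 0.0855), without WT anti-CD40 B or C (0.0617 and 0.0536) or without the low-count filter (0.0511).

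**Figure D2:**
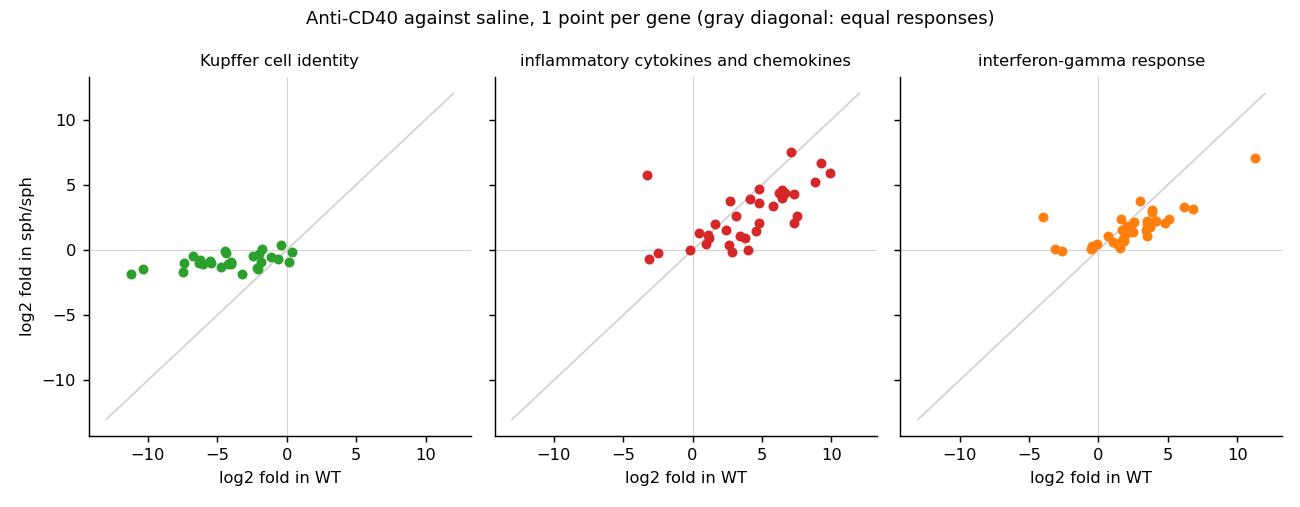
Log2 fold of anti-CD40 against saline in sph/sph (vertical axis) and in WT (horizontal axis) for each measured gene of 3 lists; the gray diagonal marks equal responses. Kupffer cell genes reach -11.18 in WT and -1.87 in sph/sph for Clec4f, and most inflammatory and interferon-gamma response genes lie above 0 in both genotypes and below the diagonal.

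The fourth comparison sets sph/sph against WT under anti-CD40. Kupffer cell genes were much higher in sph/sph: Clec4f was at 2099 ± 1581 CPM against 4.29 ± 2.82 CPM (486-fold, and 282-fold without sph/sph anti-CD40 C; SD, n = 3 per group; edgeR adjusted p = 8.82e-05), Vsig4 at 1131 ± 613 against 2.60 ± 3.86 CPM (446-fold; edgeR adjusted p = 0.00105) and Cd163 at 268 ± 150 against 0.529 ± 0.521 CPM (526-fold; edgeR adjusted p = 0.000103). Hmox1, Marco and Spic were higher as under saline: Hmox1 11.0-fold (9361 ± 3555 against 850 ± 284 CPM; edgeR adjusted p = 0.000469), Marco 30.4-fold (edgeR adjusted p = 0.000965) and Spic 11.0-fold (edgeR adjusted p = 0.000555). Lower in sph/sph were Il12b, a subunit of interleukin 12 and 23 (-4.90 ± 1.06; edgeR adjusted p = 0.0113), Ch25h (-6.72 ± 0.66; edgeR adjusted p = 0.000172) and Cd40 (-2.17 ± 0.50; edgeR adjusted p = 0.0158). Il10, an anti-inflammatory cytokine, was higher in sph/sph (36.8 ± 30.7 against 3.02 ± 0.811 CPM; edgeR adjusted p = 0.0299). In all, 1598 genes were higher and 857 lower.

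Of 29 Kupffer cell genes 20 were higher and none lower (23 when adjusted over the list alone), including Gfra2 (7.63), C6 (5.97), Slc40a1 (4.75 ± 0.41) and Adgre1 (4.10 ± 0.56). The list passed (camera adjusted p = 5.44e-38; adjusted p = 0.011 with an estimated correlation). Of 25 heme and iron genes 13 were higher and 1 lower (14 and 1 when adjusted over the list alone), and of 32 NRF2 targets 15 were higher and none lower (22 when adjusted over the list alone), with Gsta4 (4.89), Ephx1 (4.22), Me1 (3.50) and Gstm5 (2.83). Of 27 LXR target genes 15 were higher and 1 lower (17 and 1 when adjusted over the list alone), with Vldlr (a ratio of 63.1, counting interval 17.1 to 528, with 2 counts in WT) and Pltp (3.56). With an estimated correlation these lists gave adjusted p = 0.0443, 0.0442 and 0.0443 (0.0407, 0.0583 and 0.162 without sph/sph anti-CD40 C), and camera's values with the preset one were 7.89e-12, 1.72e-11 and 2.48e-07. Of 39 phagocytosis genes 22 were higher and 5 lower (the same when adjusted over the list alone), among them Marco, Colec12 (4.07), C1qc (4.05) and Itgax (-3.63), with camera adjusted p = 1.26e-08 and adjusted p = 0.0724 with an estimated correlation. Lysosome genes were higher in 11 and lower in 1 of 38 (11 and 2 when adjusted over the list alone), Man2b1 by 2.19 and Lgmn by 2.15, with camera adjusted p = 0.000174 and adjusted p = 0.568 with an estimated correlation.

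Of 34 inflammatory genes 6 were lower and 2 higher (11 and 3 when adjusted over the list alone), Il12b, Cxcl11 (-4.47), Csf1 (-3.32) and Il18 (3.55) having the largest folds. Cxcl9 stood at 494 ± 420 CPM in sph/sph and 4699 ± 1398 CPM in WT (edgeR adjusted p = 0.0667), Tnf at 47.5 ± 46.0 and 304 ± 289 CPM (0.095), Nos2 at 24.9 ± 21.3 and 440 ± 609 CPM (0.0683) and Ccl2 at 48.7 ± 43.4 and 301 ± 68.7 CPM (0.0832). DESeq2 called these 4 genes lower (adjusted p = 0.00308, 0.0154, 0.0151 and 0.012). Ccl2 was also lower by limma-voom (adjusted p = 0.0426) and without sph/sph anti-CD40 C (edgeR adjusted p = 0.00376). In the fit without that library Il6 (log2 fold -0.14, edgeR adjusted p = 0.902) and Il1b (0.12, 0.898) were not called. Tnf (edgeR adjusted p = 0.0729) and Nos2 (0.0513) were not called in it either. Of 37 NF-kB and CD40 genes 9 were lower and 1 higher (10 and 1 when adjusted over the list alone; Traf1 -2.74, Cd83 -1.65), of 38 interferon-gamma response genes 6 lower and 2 higher (8 and 3; Upp1 -3.62, Fcgr4 3.11), of 23 MHC class I genes 8 lower (9; H2-Q6 -2.52) and of 34 interferon-stimulated genes 2 lower (0; Ifi44 -2.60). Camera's adjusted p for these 5 lists lay between 4.89e-08 and 0.000115, and adjusted p = 0.568, 0.568, 0.568, 0.474 and 0.618 with an estimated correlation. Without sph/sph anti-CD40 C camera did not call the interferon-stimulated list (adjusted p = 0.157). The other lists then had camera adjusted p from 0.000414 (MHC class I) to 0.0406 (interferon-gamma response). Of 27 anti-inflammatory genes 9 were higher and 1 lower (9 and 3 when adjusted over the list alone), led by Trem2 (5.17), Folr2 (4.32), Il10 and Ccl24 (3.27), and camera did not call the list (adjusted p = 0.218). H2-Aa was at 799 ± 126 CPM in sph/sph and 2532 ± 1509 CPM in WT (edgeR adjusted p = 0.0875). It was called lower by DESeq2 (adjusted p = 0.0207) and with a term for sex, added after seeing the data (edgeR adjusted p = 0.0281). Ly6c1 was lower (-5.36 ± 0.40), as were Olr1, a receptor for oxidised lipoprotein (-5.00 ± 0.63), and Hspb1 (-4.95 ± 1.16). Of 32 immediate-early and dissociation genes 9 were lower (10 when adjusted over the list alone), Egr2 at -2.62 and Jun at -1.46 (camera adjusted p = 9.25e-06; adjusted p = 0.334 with an estimated correlation). Of 34 glycolysis genes 9 were higher, Ddit4 by 2.81, and 1 lower (10 and 3 when adjusted over the list alone). In the fit without sph/sph anti-CD40 C 20 glycolysis genes were higher and 2 lower, and 23 NRF2 genes were higher. In that fit 11 interferon-gamma response genes were lower and 4 higher, and 9 dendritic cell genes were lower and 5 higher. It also had 5 MHC class II and 5 immediate-early genes lower.

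Other cells' markers again differed with genotype. T and NK cell genes were lower in 14 of 37 (22 when adjusted over the list alone), with Prf1 at -6.12 and Xcl1 at -5.76, and endothelial genes in 6 of 27 (8 when adjusted over the list alone), with Lyve1 at -5.30; with an estimated correlation the lists gave adjusted p = 0.453 and 0.568, against camera's 6.39e-12 and 6.53e-07. Their summed levels were 223 ± 119 against 1973 ± 1629 CPM and 2649 ± 2027 against 8949 ± 4488 CPM. Erythroid genes were higher in 30 of 35 (32 when adjusted over the list alone; camera adjusted p = 1.36e-27; adjusted p = 0.0636 with an estimated correlation). Of the neutrophil list 6 genes were lower (Asprv1 -4.05) and 4 higher, among them Mpo (6.21), Ctsg (5.95) and Elane (5.72). Without sph/sph anti-CD40 C, 1893 genes were higher and 1515 lower; 34 T and NK cell and 15 endothelial genes were then lower and Cxcl9 was called too (edgeR adjusted p = 0.0158). Without WT anti-CD40 B the total of 2455 was 1540, without WT anti-CD40 C it was 1355, and with only the 6 libraries compared it was 735; in that fit Cd40, Il12b and Il10 were not called (edgeR adjusted p = 0.101, 0.0565 and 0.146), nor were Cxcl11, Traf1, Upp1, Trem2, Prf1, Mpo, Elane and Ctsg. Il10 was also not called without any 1 of WT anti-CD40 A, B and C and sph/sph anti-CD40 A and B (edgeR adjusted p from 0.0683 to 0.108).

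**Figure D3:**
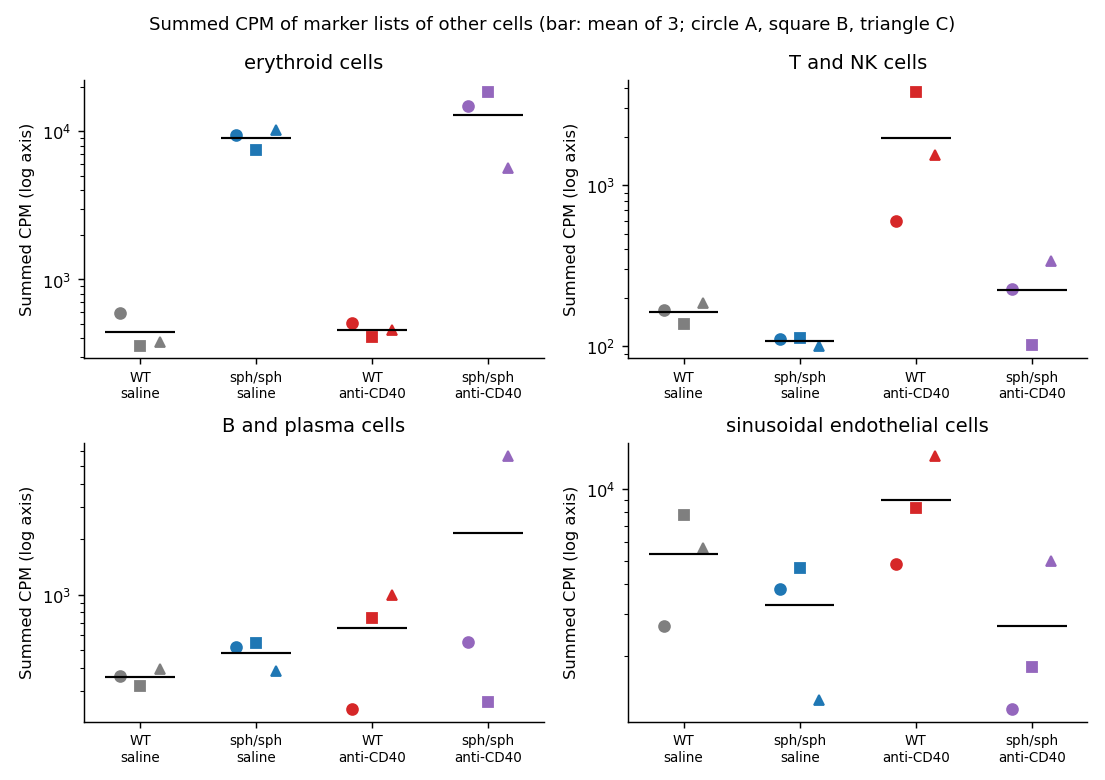
Summed CPM of the marker lists of erythroid, T and NK, B and plasma, and sinusoidal endothelial cells in each library on a log axis; the bar is the mean of 3 libraries and the symbols mark libraries A, B and C. Erythroid sums are 9040 CPM in sph/sph saline and 443 CPM in WT saline, T and NK sums reach 3774 CPM in WT anti-CD40 B, and B cell sums reach 5682 CPM in sph/sph anti-CD40 C.

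Whether the response to anti-CD40 differed between genotypes was tested by the interaction, the response of sph/sph minus that of WT. The fall of Kupffer cell genes differed: Clec4f fell 2323-fold in WT and stood 3.67-fold lower in sph/sph, a difference of 9.31 ± 0.90 on the log2 scale (edgeR adjusted p = 0.000426), and 8.53 without sph/sph anti-CD40 C. Cd207 (11.66 ± 0.92; edgeR adjusted p = 0.000168), Cd163 (11.03 ± 0.97; 0.000272) and Vsig4 (8.85 ± 1.38; 0.00716) differed likewise. On the other side Ch25h (-7.86 ± 1.08; edgeR adjusted p = 0.00347), Tnfrsf9, a co-stimulatory receptor (-7.73 ± 1.25; 0.00841), Olr1 (-6.82 ± 1.01; 0.00557) and Cst7 (-5.71 ± 1.06; 0.0152) had the larger rise in WT. In all, 440 genes were above 0 and 155 below, and 590 of these 595 genes (99.2%) had the smaller response in sph/sph. Smaller refers to the size of the log2 fold alone. Among the 590, 42 genes that rose and 49 that fell in WT had a log2 fold of opposite sign in sph/sph. Of the 595, 592 were called in WT and 18 in sph/sph.

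Of 29 Kupffer cell genes 17 had an interaction above 0 and none below (20 and 1 when adjusted over the list alone; median 3.12; camera adjusted p = 1.17e-45; adjusted p = 0.0045 with an estimated correlation). Among them were C6 (6.38), Gfra2 (6.29), Slc40a1 (4.73 ± 0.52), Timd4 (4.34 ± 0.93) and Adgre1 (4.13 ± 0.73). Timd4 was not called in 8 of the 12 fits without 1 library (edgeR adjusted p from 0.0566 to 0.0925). Of 39 phagocytosis genes 9 were above 0 (12 and 1 when adjusted over the list alone), of 25 heme and iron genes 4 (10 and 2), of 32 NRF2 targets 4 (4 and 1) and of 27 LXR genes 4 above and 2 below (10 and 3). Their camera adjusted p were 2.58e-07, 0.000193, 0.0313 and 0.00316, and adjusted p = 0.363, 0.416, 0.645 and 0.416 with an estimated correlation. For Hmox1 (0.55 ± 0.53; edgeR adjusted p = 0.628), Marco (0.81 ± 0.79; 0.634) and Spic (1.52 ± 0.54; 0.156) no difference between the responses was detected.

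Few genes of the inflammatory programs passed the interaction test by themselves: of 34 inflammatory genes 2 were below 0 (Csf1 -3.97, Cxcl1 -2.84) and 1 above (Cxcl13, a chemokine for B cells, 9.07 ± 2.09), of 38 interferon-gamma response genes 3 were below (Wars -2.40, Irf8 -1.41, Jak2 -0.98), of 37 NF-kB genes 2 (Tnip1 -1.94, Ripk2 -1.56), of 23 MHC class I genes 1 (Tap2 -1.58) and of 34 interferon-stimulated genes none. Adjusted over the list alone, 6 were below and 2 above, 4 and 2, 2 and 1, 2 and 0, and 0 and 0. Camera's adjusted p was 0.000193, 0.000193, 0.000741, 3.95e-06 and 0.0465, and adjusted p = 0.697, 0.737, 0.698, 0.645 and 0.851 with an estimated correlation. Cxcl9 (-3.03 ± 1.46; edgeR adjusted p = 0.3), Tnf (-2.52 ± 1.42; 0.382), Nos2 (-4.00 ± 2.42; 0.415), Cd40 (-1.46 ± 0.69; 0.296), Il12b (-5.25 ± 1.59; 0.0993) and Il10 (3.47 ± 1.30; 0.178) did not pass. DESeq2 called Il10 and Il12b (adjusted p = 0.0486 and 0.0066), and limma-voom called Spic (adjusted p = 0.0259). Without sph/sph anti-CD40 C Il10 was called (4.07 ± 0.50; edgeR adjusted p = 0.00222), as were Ccl2 (-1.84 ± 0.45; 0.0447) and Spic (1.88 ± 0.41; 0.0285), and 942 genes were, 859 of them (91.2%) with the smaller response in sph/sph. In that fit 5 inflammatory genes were below 0 and 2 above, 7 interferon-gamma response genes were below and 1 above, and 8 heme and iron genes were above. Il6 (0.93, edgeR adjusted p = 0.606), Il1b (1.42, 0.269) and Arg1 (-1.58, 0.572) were not called in it. Cxcl9 (edgeR adjusted p = 0.095), Tnf (0.294), Nos2 (0.337), Cd40 (0.334) and Il12b (0.0724) also stayed uncalled in that fit. Camera then did not call the interferon-stimulated list (median 0.14, adjusted p = 0.637) or the NF-kB list (adjusted p = 0.0505). The inflammatory and interferon-gamma response lists had camera adjusted p = 0.0418 and 0.0446. The count of 595 was 269, 370 and 295 without WT saline A, B and C, 259 and 274 without sph/sph saline A and B, 944, 338 and 388 without WT anti-CD40 A, B and C, and 386 without sph/sph anti-CD40 B. Cxcl13 was called in only 2 of the 12 fits without 1 library, those without WT anti-CD40 A and sph/sph anti-CD40 C. Cxcl1, Tap2, Jak2, Irf8 and Wars were each not called in 8 or more of them, and Wars was not called with the term for sex.

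The response score, the mean log2 level of genes that rose on average minus that of genes that fell, was -3.12 ± 0.11 in WT saline, -2.67 ± 0.38 in sph/sph saline, 2.52 ± 0.32 in WT anti-CD40 and -0.34 ± 0.54 in sph/sph anti-CD40 (SD, n = 3 per group). It was 5.64 higher with anti-CD40 in WT and 2.33 higher in sph/sph, or 41.4% of the difference in WT. The responses differed by -3.30 (exact two-sided permutation p = 0.01). Without sph/sph anti-CD40 C they differed by -2.37 (exact permutation p = 0.005, the smallest that its arrangements can give). Within each genotype the treated libraries lay above the saline ones, with an exact permutation p of 0.1, the smallest that 3 against 3 can give. The score's genes were chosen for their difference between treatments in these same libraries, which favours that separation.

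**Figure D4:**
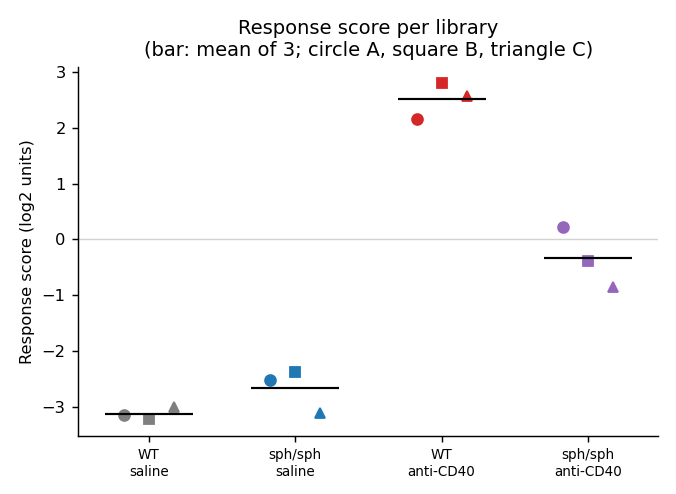
Response score per library in log2 units by group; the bar is the mean of 3 libraries and the symbols mark libraries A, B and C. WT anti-CD40 lies between 2.17 and 2.80 and sph/sph anti-CD40 between -0.85 and 0.22, above the saline libraries of both genotypes.

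Most genes called in sph/sph were also called in WT. Of the 80 genes that rose in sph/sph 78 also rose in WT (15.5 expected from independent lists), and all 28 that fell in sph/sph also fell in WT (5.52 expected), with none called in opposite directions. Over all genes the log2 folds of both responses correlated with Pearson's r of 0.710 and Spearman's rho of 0.668. Without sph/sph anti-CD40 C 1118 of 1382 risen genes (324 expected) and 844 of 990 fallen genes (231 expected) were shared, and 9 and 10 genes went opposite ways. The effects of genotype under saline and under anti-CD40 shared 154 higher genes (25.6 expected), Hmox1, Marco and Spic among them, and 23 lower genes (3.71 expected), with 3 and 6 genes called in opposite directions and a Pearson's r of 0.371.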

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

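The tests of the patterns in this part, other than those of other groupings of the libraries, were chosen after the results were seen.

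The response to anti-CD40 differed between genotypes by a test of the difference itself. The response score differed by -3.303, and 440 genes lay above 0 and 155 below in the interaction. Genes with large values above 0 were Cd207 (11.66), Cd163 (11.03), Chp2 (10.72), Clec4f (9.307), Cxcl13 (9.073), Vsig4 (8.848), Tmc3 (8.687), Cd209f (8.231), Mmp27 (7.605) and Kcnj16 (7.439). Those with large values below 0 were Ch25h (-7.856), Tubb3 (-7.751), Tnfrsf9 (-7.73), Olr1 (-6.815), Steap2 (-6.44), Adamts4 (-6.157), Sele (-6.111), Cst7 (-5.709), Mamstr (-5.623) and Il12rb2 (-5.545). Leaving out sph/sph anti-CD40 C, Cd209f was not called (5.92; edgeR adjusted p = 0.209), and Chp2 was at 8.35, Kcnj16 at 5.64, Cd207 at 10.69, Mmp27 at 6.86, Steap2 at -7.80 and Mamstr at -6.60. Cd209f had 1 count and Chp2 2 counts in WT anti-CD40, so their values are uncertain. Steap2, Sele and Mamstr were not called in some of the other fits without 1 library. Lists called above 0 by camera had medians of 3.115 (Kupffer cell identity), 0.7965 (phagocytosis), 0.7496 (heme and iron), 0.4963 (LXR targets) and 0.3667 (NRF2 targets). Lists called below 0 were those of T and NK cells (-3.603), neutrophils (-1.929), inflammatory genes (-1.852), endothelial cells (-1.245), immediate-early genes (-1.149), interferon-gamma response (-0.9331), MHC class I (-0.8244), glycolysis (-0.6332), dendritic cells (-0.5837), NF-kB and CD40 signalling (-0.5223), cholesterol synthesis (-0.4438) and interferon-stimulated genes (-0.2324). Without sph/sph anti-CD40 C the last of these had a median of 0.14 (camera adjusted p = 0.637), and the NF-kB list was not called (0.0505). Medians were then -5.27 for T and NK cells, -2.75 for endothelial and -2.17 for dendritic cells. They were -0.52 for the interferon-gamma response, -0.51 for MHC class I and -0.36 for glycolysis. The megakaryocyte list was then called too (-2.48, camera adjusted p = 2.53e-05). Of the lists called on all libraries the Kupffer cell list alone passed with an estimated correlation (adjusted p = 0.0045).

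The smaller response in sph/sph was weighed first. Library C of sph/sph anti-CD40, with saline-like levels of Cxcl9 and Tnf, does not account for it alone, since the scores still differed by -2.365 without it. Whether the injection of this mouse failed in whole or part cannot be told. Its score of -0.85 lay above every saline library. The score's genes were chosen for their response with this library among the treated ones, so that position does not show that it responded. If the injection failed, the sph/sph anti-CD40 means and the 595 calls would include an animal without the full treatment. A mixture of cells with the full WT response and cells with none requires the missing share of the fall and the reached share of the rise to add up to 1 in each library. The highest sum over the libraries was 0.634. In library A, for example, 0.265 of the fall was missing while 0.15 of the rise was reached. The genes that rose included some known from NK and cytotoxic T cells, such as Gzmc. Their low level in sph/sph lowers the reached share whatever the macrophages did, so this sum cannot decide. Among members of the program lists the highest sum was 0.717. The genes of both sums were chosen for large folds in the same WT libraries that set the full response, which can lower the reached share. Which cells expressed the members was not tested, so the second sum cannot decide either. The responses still differed without library C, but the lower T and NK cell genes in sph/sph (median -2.86) leave open whether macrophages or their surroundings differed.

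The fall of Kupffer cell genes in WT was weighed next. With a lower share of macrophages and the other cells in fixed proportions, the lists of other cells would move by a similar amount. Their medians spanned 7.92, from -1.65 for stellate cells to 6.27 for T and NK cells, which argues against that case as the sole cause. A lower share with the other cells changing by unlike amounts would also give such a range. Whether a lower share of macrophages caused the fall therefore cannot be decided by this range. Replacement of Kupffer cells by other cells predicts falls of similar size among the Kupffer cell genes; the called members spanned 10 on the log2 scale, a value that also arises where the incoming cells express some of them, so replacement and loss of expression in the same cells cannot be told apart. Monocyte genes rose in 17 and fell in 4 of 35.

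The rise of program genes in sph/sph under saline was weighed against RNA of erythroid cells. The 28 called members rose together by 27030 CPM, 379% of the rise of the haemoglobin genes (7133 CPM), but Marco and Hmox1 alone rose by 150% and 133% of it and carry most of the sum. This argues against erythroid RNA as the source of the rise of these 2 genes. For the other members, 24 of them with a rise under 10% of that of the haemoglobin genes, erythroid RNA and macrophage RNA cannot be told apart.

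Other groupings of the same libraries were tested for every count of calls. For the interaction 3 of 100 groupings, the real one included, gave as many genes as the real 595. The highest other, 1902, exchanges the genotypes in 1 treatment only and so tests the genotype effect itself. For the mean response 1 of 100 gave as many as the real 5745 (highest other 4718). Most other groupings mix the groups, which raises the spread within a group, and 89 of them called no gene in each case. These counts of genes therefore cannot decide whether chance gave the calls. For lists, 46 of 100 gave as many as the real 17 for the interaction (highest other 22) and 7 of 100 as many as the real 22 for the mean response (highest other 25), so chance cannot be excluded for these counts of lists. With pairs of groups only 10 groupings exist, too few for a share under 0.05. The real grouping was the only 1 with as many genes under saline (282, highest other 0), for anti-CD40 in WT (5420, highest other 0), for anti-CD40 in sph/sph (108, highest other 0) and for genotype under anti-CD40 (2455, highest other 757). For lists, 10 of these groupings gave as many calls under saline (12, highest other 18), 1 for anti-CD40 in WT (21, highest other 19), 3 for anti-CD40 in sph/sph (18, highest other 21) and 5 for genotype under anti-CD40 (18, highest other 21).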

How the results depend on the processing

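No paired analysis was possible because the table's columns carry no replicate numbers and nothing links the B and C libraries; the planned fits with a replicate block for genes, lists and the score were therefore not run. The A libraries of both genotypes share an identification number in each treatment, and its meaning is not given in the sources used here. The term for sex sets the A libraries apart from B and C; with it 26 named results were weaker. No named gene reversed. Without sph/sph anti-CD40 C some lists changed side: in the interaction the interferon-stimulated list, called below 0, had a median of 0.14 (camera adjusted p = 0.637), and that of B cells went from 0.55 (camera adjusted p = 0.969) to -2.70 (camera adjusted p = 0.00519). Of 11274 pairs of a named gene's result and a setting, 10131 kept direction and side of the threshold, 1057 were weaker and 86 stronger. Only results called on all libraries can become weaker, and they made up 8056 of the pairs. With 3 libraries per group and at least 14991250 counts each, simulations with few changed genes recovered from 1 (interaction) to 21 (genotype under saline) of 100 2-fold changes.

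Counts are given as higher and lower genes. With only the 6 libraries compared they were 533 and 358 for genotype under saline, 0 and 0 for anti-CD40 in sph/sph and 494 and 241 for genotype under anti-CD40. DESeq2 gave 567 and 256 for genotype under saline, 705 and 603 for anti-CD40 in sph/sph, 1474 lower for genotype under anti-CD40 and 813 and 565 for the interaction. With limma-voom they were 1179 and 764, 1304 and 878 (anti-CD40 in sph/sph), and 883 and 397 (interaction). A log2 fold of at least 1 left 1691 higher for anti-CD40 in WT, 1476 and 1289 for the mean response, and 15 shared lower genes of both genotype effects. For anti-CD40 in sph/sph, lower genes numbered 16 without a low-count filter, 49 with a stricter one, 47 without genes of other cells and mitochondria, and 16 with a term for sex, which was added after seeing the data. The cause was not tested.

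Lists called up and down with an estimated correlation numbered 2 and 0 (genotype under saline), 0 and 1 (anti-CD40 in WT), 0 and 0 (in sph/sph), 4 and 0 (genotype under anti-CD40), 1 and 0 (interaction) and 0 and 1 (mean response). Fry gave 5 and 1 under saline, 0 and 2 for anti-CD40 in sph/sph, 3 down for genotype under anti-CD40 and 0 down for the interaction.

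Leaving out 1 library in turn gave these ranges of higher and lower genes: 61 to 383 and 12 to 156 (genotype under saline), 1647 to 3297 and 2104 to 3286 (anti-CD40 in WT), 0 to 1382 and 0 to 990 (in sph/sph), 954 to 1893 and 401 to 1515 (genotype under anti-CD40), 211 to 691 and 48 to 337 (interaction), and 2276 to 3408 and 2279 to 3383 (mean response). Lists up and down ranged from 9 to 13 and 2 to 4, 11 to 15 and 6 to 8, 11 to 13 and 6 to 8, 7 to 10 and 8 to 12, 4 to 7 and 10 to 14, and 13 to 14 and 7 to 9, in the same order. The difference of the scores ranged from -3.69 to -2.365.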

Other observations

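Under anti-CD40 the neutrophil list had 6 genes lower and 4 higher in sph/sph, with a median of -0.87 (camera adjusted p = 0.0203; adjusted p = 0.568 with an estimated correlation). The higher genes were Fcnb (log2 fold 2.40) and 3 others: Mpo, the peroxidase of neutrophil granules (log2 fold 6.21; edgeR adjusted p = 0.016), Elane, a protease of the same granules (5.72; edgeR adjusted p = 0.0187), and Ctsg (5.95). Epx of eosinophils was higher by a ratio of 373 (counting interval 127 to 1814, with 3 counts in WT). With limma-voom Mpo, Elane and Epx were not called in this comparison.

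Under saline Cd163, the receptor for haemoglobin bound to haptoglobin, stood at 2432 ± 629 CPM in WT and 614 ± 178 CPM in sph/sph (edgeR adjusted p = 0.122). DESeq2 (adjusted p = 0.0107) and limma-voom (adjusted p = 0.00344) called Cd163 lower in sph/sph.

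Counts of 4 Y-linked genes, Ddx3y, Eif2s3y, Kdm5d and Uty, were 0 in library A of every group and between 2436 and 4055 in the other 8 libraries, although the labels describe male mice. Each group thus held 1 library without these transcripts, and the groups did not differ in this. Mitochondrial genes took 1.09% to 3.28% of the counts, the most in sph/sph anti-CD40 C. The quality weights of limma-voom were lowest for sph/sph anti-CD40 C (0.187) and WT anti-CD40 A (0.348).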
